A study of Mus musculus with 30 samples.

How the data were processed

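RNA was sequenced from mouse embryonic fibroblasts that lack Cry2 and stably carry c-MYC together with an empty vector (EV), wild-type CRY2 (WT) or CRY2 with the change D325H, S510L or F428D. Cells were plated at 150 (low density) or 500 (high density) per well in 3% oxygen and 15% serum and harvested on day 14 (low) or day 11 (high), per the labels. Each of the 10 groups has 3 biological replicates of 2 combined wells. The labels do not say whether the lines of a construct were derived independently, so a difference between constructs is also a difference between cell lines, and p-values measure only the spread between these samples.

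Reads were single-end, 50 nt, from a BGISEQ-500, with a stated depth of 20 M reads per library. The authors deposited 1 table of TPM (transcript abundances scaled to a fixed sum) for 34724 gene symbols in 30 columns, 26437 of them above 0 in some library. Per the submitters' processing notes the values come from kallisto (no version given) with the assembly GRCh37.p13. That is a human assembly, whereas 34095 of the symbols are in the mouse gene name table used here. The transcript set behind the values is therefore open, as is the way transcripts were summed to genes. Gene types and places were taken from GENCODE M21 (GRCm38). Whether the introduced CRY2 and c-MYC are counted under Cry2 and Myc depends on their sequence, which the sources used here do not give. kallisto shares reads among like transcripts, so values of paralogues such as Prl2c2 and Prl2c3, the Serpina1 genes and the Sprr genes are less certain.

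TPM scales each library to a fixed sum, so the depth per library is unknown and no counting error can be given; precision rests on the replicates. The values in the table sum to 960238 (D325H low 1) to 965790 (F428D low 1), median 963545, so a small part of each total lies outside the table. Genes at 1 TPM or more numbered 12182 to 12655 (median 12463.5) and genes above 0 15910 to 19269. The 13 mitochondrial genes took 1.57% (S510L low 1) to 4.47% (WT high 1) of TPM, median 2.68%, and 89 ribosomal protein genes 12.4% (F428D low 1) to 17.0% (F428D high 3), median 15.0%. The median SD of a gene within a group, in log2(TPM + 1), ran from 0.113 (EV high) to 0.266 (F428D low). Columns are headed 1 to 30 and were matched to samples only by the number that opens each sample title, and no 2 libraries were duplicates.

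Values were taken as log2(TPM + 1), and 14093 genes with TPM of at least 1 in at least 3 libraries were tested. limma 3.58.1 (R 4.3.3) fitted 1 mean per group to all 30 libraries, with empirical Bayes moderation and a variance trend, so groups of 3 share the estimate of the spread. The Benjamini-Hochberg (BH) adjusted p was called under 0.05. Comparisons were WT with EV and each changed protein with WT within a density, each changed protein with EV and with the others averaged over densities, high with low density over the 5 constructs, the difference of each construct effect between densities, and a joint F test of these differences. Comparisons that share a control share its error.

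The 22 gene lists were p53 targets, clock repressors with E-box outputs, clock activators, S phase (E2F), G2 and mitosis, MYC targets, collagen and matrix, contractile genes, YAP targets, interferon response, inflammatory secretory, hypoxia and glycolysis, cholesterol synthesis, ATF4 stress, NRF2 antioxidant, and markers of epithelial, endothelial, macrophage, skeletal muscle, neural, adipocyte and skeletal lineage cells. They were written from general knowledge. Lists with at least 5 tested members were tested in limma with camera at its preset correlation of 0.01, BH-adjusted over lists within a comparison, repeated with the correlation estimated from the data, and with fry. Of 300 list tests 124 were called as reported and 1 with an estimated correlation. Counts are given over all genes and adjusted over the list alone.

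Genes were named by rule. Cry2, Cry1, Myc, Trp53, Cdkn1a, Mdm2, Cdkn2a, Per2, Nr1d1 and Dbp come first in every comparison. Then come the 10 highest and 10 lowest differences (5 and 5 for averaged construct comparisons) among called genes with mean log2(TPM + 1) of at least 2 whose libraries do not overlap between the sides, or, for averages, that have the same sign in every part. If fewer than 5 passed, the 5 smallest p were taken, and each called list adds its 4 members of smallest p. Not every gene the rule names is printed. Predicted genes and pseudogenes were passed over but counted. The comparisons, their tests, the 22 lists and this rule were fixed before the data were examined.

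The alternatives chosen beforehand were pseudocounts of 0.1 and 5, no filter, a filter on mean TPM of at least 5 (9932 genes), quantile normalization, median-ratio scaling over genes with mean TPM of at least 10, rescaling without Cry2, Myc and mitochondrial genes, replicate number as a block, array weights, no variance trend, only the groups compared fitted, an estimated correlation, and leaving out each library. Added after seeing the data were gene-by-gene array weights, leaving out the 2 libraries with the fewest genes above 0 and leaving out liver genes. Counts within 1.5 times of each other were taken as the same. Samples were also regrouped in all 10 splits of 3 against 3 libraries, or 100 drawn splits for larger comparisons. Correlations used 100000 resamples or every order. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for the rest.

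The fit was tested on simulated D325H low and WT low values. Of 100 genes each changed by log2 1 or 2, it recovered 80% and 96%, with 5 false of 181 calls. An unchanged comparison gave 0 genes and 0 lists. Measured genes correlate and group spreads differ, so rates may differ. The first 3 principal components held 30.9%, 11.3% and 11.2% of the variance.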

Results

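Gene expression was measured in 30 libraries of Cry2-null mouse embryonic fibroblasts in 10 groups of 3 biological replicates. All cells carried c-MYC, and the groups crossed 5 constructs (empty vector, EV; wild-type CRY2, WT; and the CRY2 proteins D325H, S510L and F428D) with a low or a high plating density. CRY2 is a repressor of the circadian clock, and the title of the series places the question at P53 and cell growth. The values are TPM, which carry no read depth, so no counting error can be given for a gene. Between 12182 genes (WT low 3) and 12655 genes (D325H low 3) reached 1 TPM in a library. Genes above 0 numbered 15910 in F428D high 2 and 16258 in D325H high 3, against a median of 19002.5. Differences are log2 of TPM + 1 with the standard error, a scale that understates changes of genes with low TPM, over 14093 genes tested. TPM values are mean ± SD of 3 libraries unless another n is given, and adjusted p values are those of limma after Benjamini-Hochberg (BH) correction.

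Cry2 (chromosome 2, 92403646 to 92434043, minus strand, GRCm38, GENCODE M21), the gene the cells lack, was measured at 4.59 ± 0.878 TPM in EV low and 4.43 ± 0.518 in EV high. With WT it stood at 75.5 ± 28.0 (low) and 72.3 ± 15.6 (high), with D325H at 116 ± 19.6 and 111 ± 56.4, and with F428D at 104 ± 19.1 and 72.2 ± 12.2. S510L gave 20.7 ± 7.22 TPM (low) and 27.6 ± 10.4 TPM (high). The lowest Cry2 value among the 24 libraries with a CRY2 construct was 13.2 TPM and the highest among the 6 EV libraries 5.55. Against WT, Cry2 was lower with S510L, at -1.80 ± 0.34 at low density (limma, BH-adjusted p = 0.000539) and -1.39 ± 0.34 at high density (adjusted p = 0.0116), and was not called with D325H (adjusted p = 0.14 and 0.396) or F428D (0.808 and 1). The S510L call at high density ended without WT high 1 (adjusted p = 0.0653), S510L high 1 (0.0558) or S510L high 2 (0.0752). The part of Cry2 that the null allele lacks is not given, and the TPM do not separate the introduced transcript from what remains of the endogenous one.

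WT was compared with EV to see what the wild-type protein changes in Cry2-null cells. With WT at low density Col9a1 and Col9a2 (chains of type IX collagen) stood at 1.08 ± 0.842 against 61.2 ± 38.2 TPM and 5.02 ± 4.33 against 88.2 ± 49.8 TPM, differences of -4.70 ± 0.88 and -3.97 ± 0.77. The rest of the 10 lowest were Snorc -4.50, Hapln1 -3.95, Col11a2 -3.80, Mest -3.70, Acan -3.43, Panx3 -3.23, Ecrg4 -3.10 and Comp -2.89, Acan being the main cartilage proteoglycan (limma, BH-adjusted p = 0.03 to 0.0464 for the 10). Cry2 was higher by 3.71 ± 0.34 (adjusted p = 1.73e-06), and Sertad1 by 0.35 ± 0.08 (adjusted p = 0.0452). These were the only 2 higher genes, with 41 lower, of 14093 tested.

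Among the other genes fixed in advance, the differences were Trp53 0.10, Cdkn1a 0.32, Mdm2 -0.21, Cdkn2a 0.05, Myc 0.21, Cry1 -0.17, Nr1d1 0.33 and Dbp -0.24, and Per2 differed by less than 0.01, none of them called (limma, adjusted p = 0.96 to 1). Of 27 tested p53 target genes, 0 were higher and 0 lower (0 and 1 adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.528). Of 10 skeletal lineage genes, 0 were higher and 3 lower (0 and 5 adjusted over the list alone). The median was -0.90 (camera adjusted p = 5.81e-06, adjusted p = 0.179 with an estimated correlation). The 18 hypoxia and glycolysis genes gave 0 higher and 0 lower of 18 (0 and 10 adjusted over the list alone). The median was -0.40 (camera adjusted p = 1.13e-11, adjusted p = 0.0112 with an estimated correlation), the only 1 of 300 list tests that stayed called with an estimated correlation. In that list Car9, a carbonic anhydrase, was at 11.2 ± 4.11 against 39.3 ± 2.60 TPM (adjusted p = 0.205), and Egln3, P4ha2 and Tpi1 stood at -1.11, -0.84 and -0.93 (adjusted p = 0.0917 to 0.227). Collagen and matrix genes gave 0 higher and 1 lower of 20 (0 and 2 adjusted over the list alone), the called member being Postn (-2.81 ± 0.59, limma, adjusted p = 0.0415). The median was -0.30 (camera adjusted p = 0.00165, adjusted p = 0.923 with an estimated correlation). Every gene call of this comparison named here except that of Cry2 ended without EV low 2, EV low 3, WT low 1 or WT low 3 (Col9a1 adjusted p = 0.227, 0.147, 0.104 and 0.105), and the count of 43 became 2, 2, 2 and 3 in these fits and 85 without EV low 1. The count was 5 without the filter on low values, 12 with a pseudocount of 5, 19 without the variance trend, 27 after quantile normalization and 2 with only these 6 libraries fitted, where Cry2 itself was not called (adjusted p = 0.0637).

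At high density 4 genes differed between WT and EV. Cry2 was higher by 3.74 ± 0.34 (limma, BH-adjusted p = 1.49e-06). Kcnj8 and Abcc9, 2 subunits of a potassium channel, were at 0.298 ± 0.0330 against 3.13 ± 0.975 TPM and 0.635 ± 0.214 against 4.58 ± 0.254 TPM (-1.64 ± 0.28, limma, adjusted p = 0.0189, and -1.78 ± 0.31, adjusted p = 0.0249). The fourth, the predicted gene Gm15280, named after its values were seen, was lower, at -1.44 ± 0.22 (adjusted p = 0.00617). At unadjusted p under 0.05 limma listed 979 genes. Next in order of p, Fam13a (-1.04) and Dnajc28 (-0.82) were not called (adjusted p = 0.151 each), nor were Trp53 0.02, Cdkn1a 0.54, Mdm2 0.53, Cdkn2a -0.54, Myc -0.17, Cry1 -0.18, Per2 -0.16, Nr1d1 0.28 and Dbp -0.33 (adjusted p = 0.745 to 1). The p53 target genes gave 0 higher and 0 lower of 27 (0 and 1 adjusted over the list alone), the member past the threshold within the list being Sesn1, which moved against it (-0.49). The median was 0.25 (camera adjusted p = 0.000956, adjusted p = 0.864 with an estimated correlation). Hypoxia and glycolysis genes gave 0 higher and 0 lower of 18 (0 and 1 adjusted over the list alone). The median was -0.25 (camera adjusted p = 0.000168, adjusted p = 0.398 with an estimated correlation). The difference between densities in the WT effect was called for 0 genes (337 at unadjusted p under 0.05, limma), and Acan, at 3.20 ± 1.00, had an adjusted p of 1. The Kcnj8 call ended in 5 of the 6 fits without 1 library (adjusted p = 0.0722 to 0.275) and with a pseudocount of 0.1 (0.299). The Abcc9 call ended without any 1 of the 6 libraries (0.0722 without WT high 2 to 0.314 without WT high 3).

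D325H was compared with WT to separate the changed protein from the wild-type one. At low density Trp53 (chromosome 11, 69580359 to 69591873, plus strand), the gene for p53, was at 54.8 ± 66.3 TPM with D325H and 281 ± 45.5 with WT, a difference of -3.02 ± 0.52 (limma, BH-adjusted p = 0.000287). The 3 D325H libraries held 15.4, 17.7 and 131 TPM of Trp53. Cdkn1a (chromosome 17, 29090976 to 29100727, plus strand), which encodes the p53-induced cell cycle inhibitor p21, was at 111 ± 149.9 against 580.5 ± 28.2 TPM (-3.37 ± 0.58, limma, adjusted p = 0.000294), with 27.3, 21.0 and 284 TPM in the D325H libraries. Mdm2, the ligase that degrades p53, was lower, at -1.81 ± 0.31 (adjusted p = 0.000267), as were the cell death genes Bax (-1.86 ± 0.27, adjusted p = 6.6e-05) and Bbc3 (-1.42 ± 0.19, adjusted p = 2.67e-05). Of the 27 p53 target genes, 2 were higher and 22 lower (2 and 22 adjusted over the list alone). The median was -1.42 (camera adjusted p = 7.04e-12, adjusted p = 0.197 with an estimated correlation). Sesn1 (0.95, adjusted p = 2.31e-05) and Plk2 (0.97, adjusted p = 0.0196) were the 2 higher members. When only these 6 libraries were fitted, 247 genes were called, 218 higher and 29 lower, and Trp53, Cdkn1a and Mdm2 were not (limma, adjusted p = 0.0952, 0.103 and 0.0647), at the same differences.

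In all, 4081 genes differed between D325H and WT at low density, 2090 higher (51.2%) and 1991 lower, and 47.9% and 57.3% were higher after quantile and median-ratio scaling. The 10 highest were Mfap4 6.49, Igf2 6.33, Mest 6.07, Penk 6.06, Postn 5.84, Gpx3 5.06, Aoc3 4.84, Col8a2 4.54, Cnmd 4.52 and Col9a1 4.49 (limma, BH-adjusted p = 8.09e-07 to 0.00398). Mfap4, a microfibril protein, was at 117 ± 86.2 against 0.0289 ± 0.0251 TPM, Igf2, a growth factor, at 991 ± 639 against 12.1 ± 11.9 TPM, and Postn, a matrix protein, at 4449 ± 1761 against 75.8 ± 30.4 TPM. The 10 lowest were Ass1 -3.53, Prl2c2 -3.43, Prl2c3 -3.41, Cdkn1a -3.37, Cd80 -3.31, Selp -3.26, Eda2r -3.13, Lmo1 -3.03, Trp53 -3.02 and Col10a1 -3.01 (limma, BH-adjusted p = 0.000287 to 0.0108), Ass1 being an enzyme of arginine synthesis (56.7 ± 77.9 against 332 ± 25.5 TPM) and Prl2c2 and Prl2c3 proliferins. Cdkn2a, which encodes p16 and p19Arf, was higher by 0.81 ± 0.28 (adjusted p = 0.0351), and the clock genes Per2 by 0.74 ± 0.17 (adjusted p = 0.00299) and Dbp by 1.27 ± 0.36 (adjusted p = 0.0108), while Cry1 0.38, Nr1d1 0.02 and Myc -0.52 were not called (limma, adjusted p = 0.105 to 0.971). The Cdkn2a call ended without WT low 1 (0.174), WT low 2 (0.102), D325H low 1 (0.14) or D325H low 2 (0.153) and after quantile normalization (0.0613), and that of Dbp without WT low 1 (0.0639), D325H low 1 (0.051) or D325H low 2 (0.0629). The count became 2505 without WT low 1, 2184 without D325H low 1 and 2536 without D325H low 2.

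Several gene lists moved with D325H at low density. Of 20 collagen and matrix genes, 17 were higher and 0 lower (17 and 1 adjusted over the list alone), with Col1a1 at 4125 ± 1744 against 696 ± 212 TPM and Fn1 the member lower within the list (-0.58). The median was 1.74 (camera adjusted p = 4.64e-11, adjusted p = 0.197 with an estimated correlation). Of 10 skeletal lineage genes, 4 were higher and 1 lower (5 and 1 adjusted over the list alone). The median was 0.49 (camera adjusted p = 0.0661). Contractile genes under serum response factor gave 11 higher and 0 lower of 14 (13 and 0 adjusted over the list alone), with Myl9, a myosin light chain, at 786 ± 335 against 94.8 ± 14.9 TPM. The median was 1.44 (camera adjusted p = 2.82e-10, adjusted p = 0.197 with an estimated correlation). MYC target genes gave 0 higher and 22 lower of 23 (0 and 23 adjusted over the list alone), among them Npm1 (-0.74) and Cad (-1.12). The median was -0.79 (camera adjusted p = 1.77e-10, adjusted p = 0.287 with an estimated correlation). Clock repressors and E-box outputs gave 6 higher and 0 lower of 11 (9 and 0 adjusted over the list alone), with Per3 1.27 and Bhlhe40 1.19. The median was 0.74 (camera adjusted p = 0.000261, adjusted p = 0.264 with an estimated correlation). Hypoxia and glycolysis genes gave 8 higher and 1 lower of 18 (9 and 1 adjusted over the list alone), Ldha being lower (-0.46), with Car9 at 144 ± 82.8 against 11.2 ± 4.11 TPM. The median was 0.62 (camera adjusted p = 0.000261, adjusted p = 0.197 with an estimated correlation). Interferon response genes gave 9 higher and 0 lower of 15 (10 and 0 adjusted over the list alone). The median was 0.90 (camera adjusted p = 5.21e-05, adjusted p = 0.287 with an estimated correlation). ATF4 stress genes gave 0 higher and 10 lower of 17 (0 and 10 adjusted over the list alone). The median was -0.37 (camera adjusted p = 0.00153, adjusted p = 0.334 with an estimated correlation). NRF2 antioxidant genes gave 0 higher and 8 lower of 11 (0 and 9 adjusted over the list alone), including Gclc (-2.53) and Hmox1 (-1.53). The median was -0.83 (camera adjusted p = 4.28e-05, adjusted p = 0.227 with an estimated correlation). Genes of G2 and mitosis gave 0 higher and 1 lower of 22 (0 and 0 adjusted over the list alone). The median was -0.46 (camera adjusted p = 0.00587, adjusted p = 0.573 with an estimated correlation). S phase genes gave 0 higher and 2 lower of 27 (0 and 2 adjusted over the list alone), the ribonucleotide reductase gene Rrm2 being lower, at -2.16 ± 0.50 (limma, adjusted p = 0.00277). The median was -0.43 (camera adjusted p = 0.00259, adjusted p = 0.573 with an estimated correlation).

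**Figure D1:**
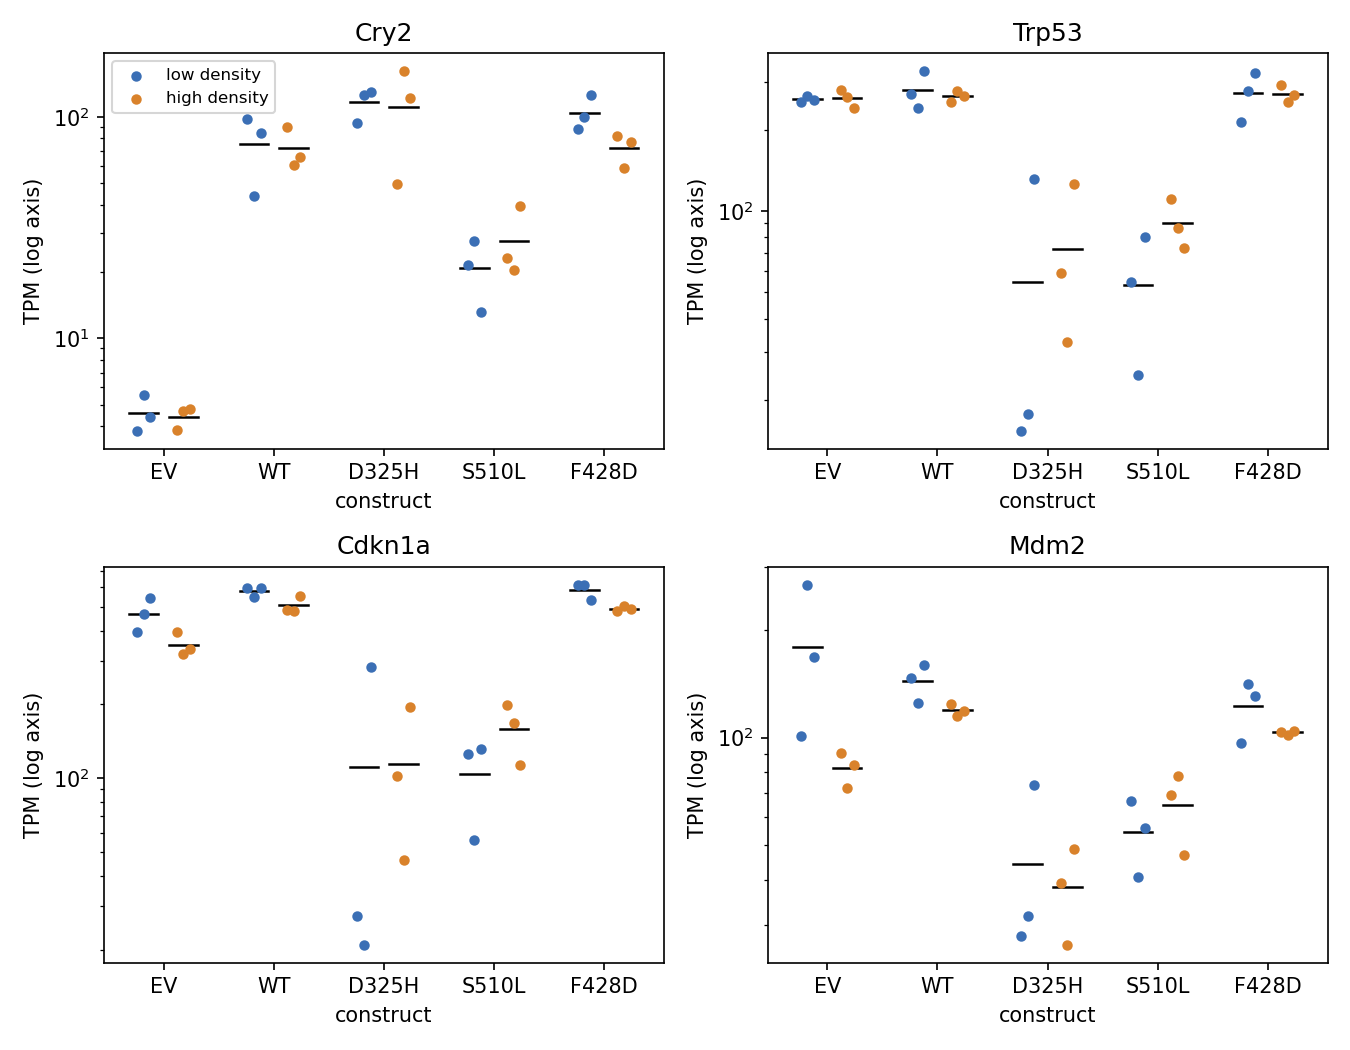
TPM on a log axis of Cry2, Trp53, Cdkn1a and Mdm2 in the 10 groups, each point a library and each bar the mean of 3 libraries. Trp53 stood between 15.4 and 131 TPM in the D325H low libraries, against a mean of 281 TPM in WT low.

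At high density D325H differed from WT in 1436 genes, 770 higher and 666 lower. Trp53 was at 72.5 ± 48.0 against 266 ± 12.8 TPM (-2.07 ± 0.52, limma, BH-adjusted p = 0.015), Cdkn1a at 115 ± 75.4 against 508 ± 40.5 TPM (-2.36 ± 0.58, adjusted p = 0.0135) and Mdm2 at 38.1 ± 11.3 against 119 ± 4.47 TPM (-1.66 ± 0.31, adjusted p = 0.00291). Btg2, an antiproliferative p53 target, was lower, at -1.51 ± 0.23 (limma, adjusted p = 0.000763). Of the 27 p53 target genes, 1 was higher and 20 lower (1 and 21 adjusted over the list alone), the higher member again being Sesn1 (0.77). The median was -1.23 (camera adjusted p = 2.8e-14, adjusted p = 0.33 with an estimated correlation). The 10 highest genes were Postn 4.76, Mest 4.51, Mfap4 3.88, Penk 3.66, Igf2 3.65, Gpx3 3.46, Susd2 3.20, Aoc3 3.12, Cdkn1c 3.08 and Cxcl12 2.94, Cdkn1c encoding the cell cycle inhibitor p57 (140.2 ± 67.5 against 14.2 ± 2.47 TPM). Among the lowest were Prl2c3 -3.78, Prl2c2 -3.31, Col10a1 -3.23, Selp -3.04, Anxa8 -2.77, Perp -2.58, Gdf15 -2.56, Slc16a11 -2.46 and Vnn1 -2.46, Col10a1 being the collagen of hypertrophic cartilage and Gdf15 a stress-induced cytokine (limma, adjusted p = 0.000148 to 0.0471 for those named). Cdkn2a was higher by 1.05 ± 0.28 (adjusted p = 0.0222) and Per2 by 0.72 ± 0.17 (adjusted p = 0.0108), and Cry1 0.31, Myc 0.29, Nr1d1 -0.24 and Dbp 1.00 were not called (adjusted p = 0.074 to 0.686). Without D325H high 2 the count was 253 and Trp53, Cdkn1a, Cdkn2a and Per2 lost their calls (limma, adjusted p = 0.125, 0.118, 0.131 and 0.107), as they did without WT high 3 (0.056, 0.0568, 0.0763 and 0.0526), while without WT high 1 Trp53 (0.0517) and Cdkn2a (0.0992) did. The count was 491 without WT high 1, 903 without WT high 2 and 479 without WT high 3, and D325H high 3 is a library with few genes above 0 (16258).

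Among the lists at high density, cholesterol synthesis genes gave 8 higher and 0 lower of 20 (14 and 0 adjusted over the list alone), with Hmgcs1, which makes the precursor of mevalonate, at 90.8 ± 1.83 against 47.7 ± 2.24 TPM. The median was 0.45 (camera adjusted p = 1.08e-06, adjusted p = 0.33 with an estimated correlation). Collagen and matrix genes gave 6 higher and 1 lower of 20 (11 and 1 adjusted over the list alone), Fn1 being lower (-0.77). The median was 0.82 (camera adjusted p = 4.5e-05, adjusted p = 0.33 with an estimated correlation). Contractile genes gave 6 higher and 0 lower of 14 (9 and 0 adjusted over the list alone). The median was 0.78 (camera adjusted p = 4.5e-05, adjusted p = 0.33 with an estimated correlation). Hypoxia and glycolysis genes gave 3 higher and 0 lower of 18 (6 and 0 adjusted over the list alone). The median was 0.24 (camera adjusted p = 0.00146, adjusted p = 0.33 with an estimated correlation). ATF4 stress genes gave 0 higher and 4 lower of 17 (0 and 4 adjusted over the list alone). The median was -0.38 (camera adjusted p = 0.000402, adjusted p = 0.33 with an estimated correlation). Clock repressors and E-box outputs gave 3 higher and 0 lower of 11 (5 and 0 adjusted over the list alone). The median was 0.44 (camera adjusted p = 0.00146, adjusted p = 0.33 with an estimated correlation). MYC target genes gave 0 higher and 2 lower of 23 (0 and 3 adjusted over the list alone). The median was -0.41 (camera adjusted p = 3.76e-06, adjusted p = 0.393 with an estimated correlation). Interferon genes gave 1 higher and 0 lower of 15 (3 and 0 adjusted over the list alone). The median was 0.26 (camera adjusted p = 0.041, adjusted p = 0.57 with an estimated correlation). NRF2 genes gave 0 higher and 2 lower of 11 (0 and 3 adjusted over the list alone). The median was -0.42 (camera adjusted p = 0.0025, adjusted p = 0.334 with an estimated correlation). A difference between densities in the D325H effect was called for 0 genes (913 at unadjusted p under 0.05, limma), Trp53 standing at 0.95 ± 0.74 (adjusted p = 0.822) and Cdkn1a at 1.01 ± 0.83 (0.832).

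S510L was compared with WT in the same way. At low density Col9a1 with S510L was at 327 ± 25.4 against 1.08 ± 0.842 TPM (7.38 ± 0.88, limma, BH-adjusted p = 3.77e-06) and Matn1, a cartilage matrix protein, at 195 ± 17.1 against 0.257 ± 0.321 TPM (7.31 ± 0.67, adjusted p = 1.85e-07). Col2a1, the main collagen of cartilage, was at 3703 ± 153 against 496 ± 187 TPM (2.98 ± 0.32, adjusted p = 1.18e-06), and its regulator Sox9 was higher at 1.69 (limma, adjusted p = 0.000208). The rest of the 10 highest were Cnmd 7.08, Snorc 7.08, Hapln1 6.28, Rtl3 6.24, Igf2 6.11, Col11a2 6.05, Col9a2 5.84 and Mest 5.67 (adjusted p = 2.52e-06 to 7.27e-05). Trp53 was at 53.2 ± 27.8 TPM, with 54.6, 24.7 and 80.3 in the 3 libraries, against 281 ± 45.5 with WT (-2.52 ± 0.52, limma, adjusted p = 0.00125). Cdkn1a (-2.56 ± 0.58, adjusted p = 0.00286) and Mdm2 (-1.41 ± 0.31, adjusted p = 0.00208) were lower too. The other 8 of the 10 lowest were Sprr1a -3.38, Sprr2k -3.08, Cox6b2 -2.88, Slc16a11 -2.84, Alpl -2.79, Glipr1 -2.60, Cd80 -2.58 and Dglucy -2.58 (limma, adjusted p = 3.26e-05 to 0.0492), Alpl being the alkaline phosphatase of bone (19.9 ± 7.95 against 140.2 ± 45.8 TPM) and Sprr1a a cornified envelope protein. Dbp was higher by 1.43 ± 0.36 (adjusted p = 0.00574) and Nr1d1 by 1.05 ± 0.33 (adjusted p = 0.0238), and Cry1 0.39, Myc -0.14, Cdkn2a 0.76 and Per2 -0.06 were not called (limma, adjusted p = 0.0574 to 0.84). In all 3277 genes differed, 2107 higher (64.3%) and 1170 lower, and after quantile normalization 50.1% of the calls were higher. The count became 2101 without S510L low 1, 2054 without S510L low 2 and 1182 with only these 6 libraries fitted, and the Sprr1a call ended without WT low 1 (adjusted p = 0.105), S510L low 1 (0.0509) or S510L low 2 (0.0547). The Dbp call ended without S510L low 1 (0.062), and that of Nr1d1 without WT low 1 (0.0508), WT low 2 (0.103), S510L low 1 (0.248) or S510L low 2 (0.0577).

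Among the lists at low density, the 10 skeletal lineage genes gave 7 higher and 1 lower of 10 (7 and 1 adjusted over the list alone), Alpl moving against the rest. The median was 2.34 (camera adjusted p = 0.000277, adjusted p = 0.372 with an estimated correlation). The 27 p53 target genes gave 2 higher and 19 lower of 27 (2 and 21 adjusted over the list alone), with Sesn1 (0.86) and Plk2 (0.89) higher. The median was -1.41 (camera adjusted p = 1.58e-11, adjusted p = 0.372 with an estimated correlation). Cholesterol synthesis genes gave 16 higher and 0 lower of 20 (17 and 0 adjusted over the list alone), with Insig1, a sterol-regulated gene, at 53.7 ± 12.4 against 20.6 ± 3.03 TPM. The median was 0.69 (camera adjusted p = 9.6e-09, adjusted p = 0.389 with an estimated correlation). Hypoxia and glycolysis genes gave 8 higher and 0 lower of 18 (10 and 0 adjusted over the list alone), including Egln3 (2.40). The median was 0.30 (camera adjusted p = 2.79e-05, adjusted p = 0.333 with an estimated correlation). Collagen and matrix genes gave 11 higher and 1 lower of 20 (14 and 1 adjusted over the list alone), with Fn1 lower (-0.84). The median was 0.98 (camera adjusted p = 0.000147, adjusted p = 0.437 with an estimated correlation). Contractile genes gave 7 higher and 0 lower of 14 (8 and 0 adjusted over the list alone). The median was 0.62 (camera adjusted p = 0.00664, adjusted p = 0.589 with an estimated correlation). Clock repressors and E-box outputs gave 6 higher and 0 lower of 11 (6 and 0 adjusted over the list alone), with Bhlhe41 2.48 and Bhlhe40 1.34. The median was 0.60 (camera adjusted p = 0.00232, adjusted p = 0.437 with an estimated correlation). MYC target genes gave 0 higher and 2 lower of 23 (0 and 0 adjusted over the list alone). The median was -0.39 (camera adjusted p = 0.000173, adjusted p = 0.589 with an estimated correlation). NRF2 genes gave 0 higher and 3 lower of 11 (0 and 7 adjusted over the list alone). The median was -0.50 (camera adjusted p = 0.00075, adjusted p = 0.437 with an estimated correlation).

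At high density S510L differed from WT in 1293 genes, 1042 higher (80.6%) and 251 lower, and the higher share was 54.8% after quantile normalization and 53.7% after median-ratio scaling, which moved the median of all genes by -0.104 and -0.103. Acan was at 140.5 ± 28.1 against 3.77 ± 1.82 TPM (4.95 ± 0.71, limma, BH-adjusted p = 0.000175), Col9a1 at 90.8 ± 37.1 against 0.995 ± 0.249 TPM and Col2a1 at 1501 ± 317 against 337 ± 77.3 TPM. The rest of the 10 highest were C1qtnf3 4.92, Cnmd 4.92, Hapln1 4.75, Snorc 4.71, Matn1 4.71, Rtl3 4.46, Col9a2 4.40 and Col11a2 4.40 (limma, adjusted p = 0.000172 to 0.00633). The 10 lowest were Cox6b2 -2.13, Prg4 -2.08, Sncg -1.98, Ltc4s -1.88, Alpl -1.79, Dglucy -1.72, Hmcn2 -1.71, Slc16a10 -1.70, Dcxr -1.64 and Efna3 -1.63 (adjusted p = 0.00081 to 0.0414), Prg4 being lubricin of the joint surface (2.67 ± 0.267 against 14.7 ± 3.04 TPM) and Dcxr a xylulose reductase. Trp53 was at 90.3 ± 18.9 against 266 ± 12.8 TPM and was not called (-1.57 ± 0.52, limma, adjusted p = 0.0605), nor were Cdkn1a (-1.70 ± 0.58, adjusted p = 0.0685) and Mdm2 (-0.90 ± 0.31, adjusted p = 0.0687). Of the 27 p53 target genes, 1 was higher and 13 lower (2 and 19 adjusted over the list alone), among them Bbc3 (-1.18 ± 0.19, limma, adjusted p = 0.000435) and Btg2 (-1.18 ± 0.23, adjusted p = 0.00247), with Sesn1 higher (0.62). The median was -1.02 (camera adjusted p = 9.32e-14, adjusted p = 0.498 with an estimated correlation). The genes Cry1 0.53, Myc -0.25, Cdkn2a 0.34, Per2 0.02, Nr1d1 -0.32 and Dbp -0.34 were not called (adjusted p = 0.0578 to 0.975). Liver transcripts were measured in these libraries, Alb at 7.31 TPM against 0.310 in WT, and 13 genes of a liver list chosen after the values were seen were among the higher calls. The Alpl call ended in each fit without 1 of the 6 libraries, and the count was 665, 699 and 634 without WT high 1, 2 and 3, 656 and 572 without S510L high 1 and 2, and 2852 with only these 6 libraries fitted.

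Among the lists at high density, cholesterol synthesis genes gave 8 higher and 0 lower of 20 (12 and 0 adjusted over the list alone), with Insig1 (0.93) higher. The median was 0.45 (camera adjusted p = 1.43e-05, adjusted p = 0.788 with an estimated correlation). Skeletal lineage genes gave 6 higher and 1 lower of 10 (7 and 1 adjusted over the list alone), Alpl being lower (-1.79). The median was 1.64 (camera adjusted p = 0.00186, adjusted p = 0.562 with an estimated correlation). Adipocyte markers gave 0 higher and 1 lower of 8 (0 and 3 adjusted over the list alone), the lower one being Fabp4 (-1.61). The median was -0.57 (camera adjusted p = 0.00186, adjusted p = 0.562 with an estimated correlation). Genes of G2 and mitosis gave 2 higher and 0 lower of 22 (2 and 0 adjusted over the list alone), with Nusap1 at 0.92. The median was 0.58 (camera adjusted p = 0.00188, adjusted p = 0.788 with an estimated correlation). Clock repressors and E-box outputs gave 0 higher and 0 lower of 11 (0 and 0 adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.928). A difference between densities in the S510L effect was called for 10 genes, 5 higher and 5 lower at high density. The higher ones were the liver genes Alb (2.94, limma, BH-adjusted p = 3e-04), Apoa1 (1.91, 0.000114), Fabp1 (1.34, 0.000151), Ahsg (1.23, 0.00241) and Serpina1b (1.09, 0.00732). The lower ones, of which those outside the naming rule were named after their values were seen, were Chrdl2 (-2.94, adjusted p = 0.000201), a BMP antagonist at 10.9 ± 5.85 TPM in S510L low and 0.488 ± 0.311 in S510L high, Nrk (-2.25, 0.00241), Mgll (-1.57, 0.0301), Ninj2 (-1.51, 0.0075) and Septin5 (-1.08, 0.0301). For Trp53 the difference was 0.95 ± 0.74 (limma, adjusted p = 0.686).

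**Figure D2:**
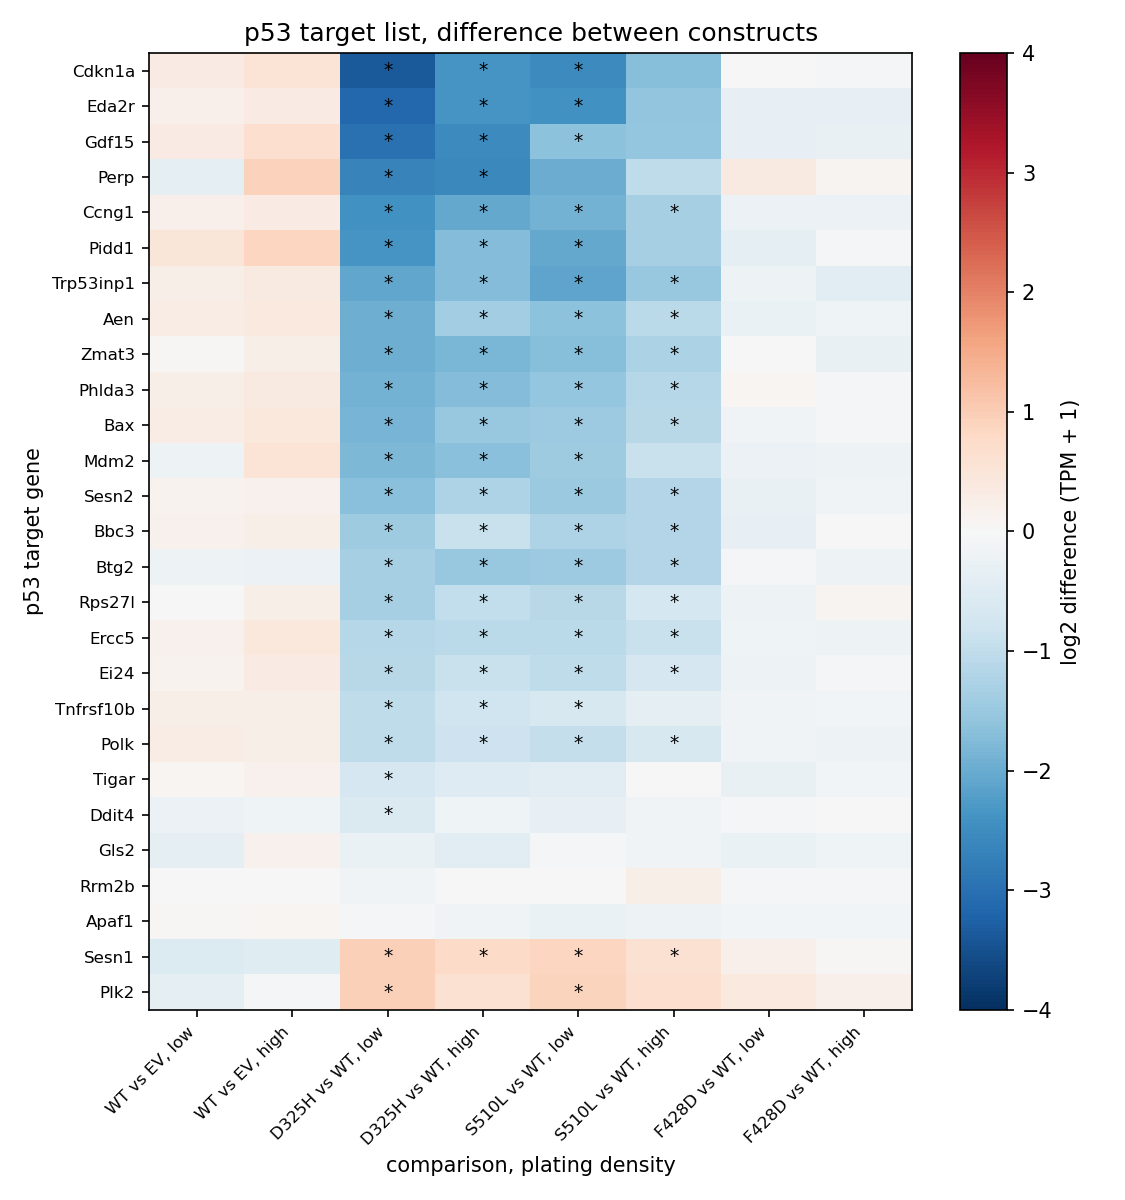
Log2 difference in TPM + 1 of the 27 tested p53 target genes (vertical axis) in the 8 comparisons within a density (horizontal axis), stars marking adjusted p under 0.05. With D325H at low density 22 of 27 were lower, and with F428D 0 of 27 at either density.

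F428D differed from WT at low density in 2 genes, with 911 at unadjusted p under 0.05 (limma). Cry1 (chromosome 10, 85131700 to 85185064, minus strand), the paralogue of Cry2, was at 3.27 ± 1.75 against 7.81 ± 0.622 TPM (-1.12 ± 0.18, limma, BH-adjusted p = 0.0225). Sox6, a transcription factor of cartilage, was at 9.47 ± 3.78 against 1.85 ± 1.07 TPM (1.90 ± 0.33, adjusted p = 0.0428). Next in order of p, Mdm4, a p53 inhibitor, was at 27.2 ± 7.18 against 59.7 ± 24.1 TPM (limma, adjusted p = 0.128) and was not called, nor were Pdlim4 (1.25) and Tmem47 (1.06), both at adjusted p = 0.298. Trp53 was at 273 ± 55.9 TPM and Cdkn1a at 588 ± 46.9, and Trp53 -0.05, Cdkn1a 0.02, Mdm2 -0.24, Cdkn2a -0.63, Myc -0.40, Per2 -0.28, Nr1d1 0.43 and Dbp 0.06 were not called (adjusted p = 0.73 to 1). Of the p53 target genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone). The median was -0.17 (camera adjusted p = 0.168). Skeletal lineage genes gave 0 higher and 0 lower of 10 (6 and 0 adjusted over the list alone), with Acan at 2.24 and Col2a1 at 1.04. The median was 0.91 (camera adjusted p = 7.84e-06, adjusted p = 0.383 with an estimated correlation). MYC target genes gave 0 higher and 0 lower of 23 (0 and 0 adjusted over the list alone). The median was -0.35 (camera adjusted p = 2.17e-08, adjusted p = 0.604 with an estimated correlation). Adipocyte markers gave 0 higher and 0 lower of 8 (0 and 1 adjusted over the list alone). The median was -0.77 (camera adjusted p = 0.000635, adjusted p = 0.604 with an estimated correlation). The Cry1 call ended without WT low 1 (limma, adjusted p = 0.108), WT low 3 (0.0547), F428D low 1 (0.102) or F428D low 3 (0.117) and with only these 6 libraries fitted (1). The Sox6 call ended in those 4 fits (0.108, 0.427, 0.184 and 0.133), with a pseudocount of 0.1 (0.138) and without the filter on low values (0.0561), and F428D low had the widest spread of the 10 groups, a median SD of 0.266 in log2.

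At high density F428D differed from WT in 9 genes, all higher and all in the liver list chosen after the values were seen. Alb, the serum albumin gene, was at 7.29 ± 1.86 against 0.310 ± 0.153 TPM (2.65 ± 0.27, limma, BH-adjusted p = 5.29e-06), Apoa1 at 2.71 ± 0.0833 against 0.0467 ± 0.0404 TPM (1.83 ± 0.15, adjusted p = 2.56e-07), Fabp1 was higher by 1.32 ± 0.11 (adjusted p = 2.56e-07), Ahsg by 1.17 ± 0.13 (adjusted p = 2.25e-05) and Serpina1b by 0.98 ± 0.13 (adjusted p = 0.000241). The other 4, named after their values were seen, were Trf (1.52), Cyp2e1 (1.23), Serpina1c (1.09) and Serpina1a (0.92). In the 6 libraries of S510L high and F428D high Alb stood between 5.91 and 9.41 TPM, against 0 to 1.38 in the other 24. The genes Cry1 -0.64, Trp53 0.03, Cdkn1a -0.05, Mdm2 -0.20, Cdkn2a -0.30, Myc -0.25, Per2 -0.18, Nr1d1 0.07 and Dbp -0.45 were not called (limma, adjusted p = 0.603 to 1), with 773 genes at unadjusted p under 0.05. Of the p53 target genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.832). A difference between densities in the F428D effect was called for 5 genes, Apoa1 (1.86 ± 0.22), Fabp1 (1.32 ± 0.16), Alb (2.42 ± 0.39), Ahsg (1.12 ± 0.19) and Serpina1b (0.98 ± 0.18), and for Cry1 it was 0.48 ± 0.25 (limma, adjusted p = 1). The count was 37 (33 higher and 4 lower) without the filter on low values, 3 (2 and 1) with only these 6 libraries fitted and 0 with the liver list left out or with a filter on mean TPM of at least 5, and F428D high 2 had the fewest genes above 0 (15910).

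**Figure D3:**
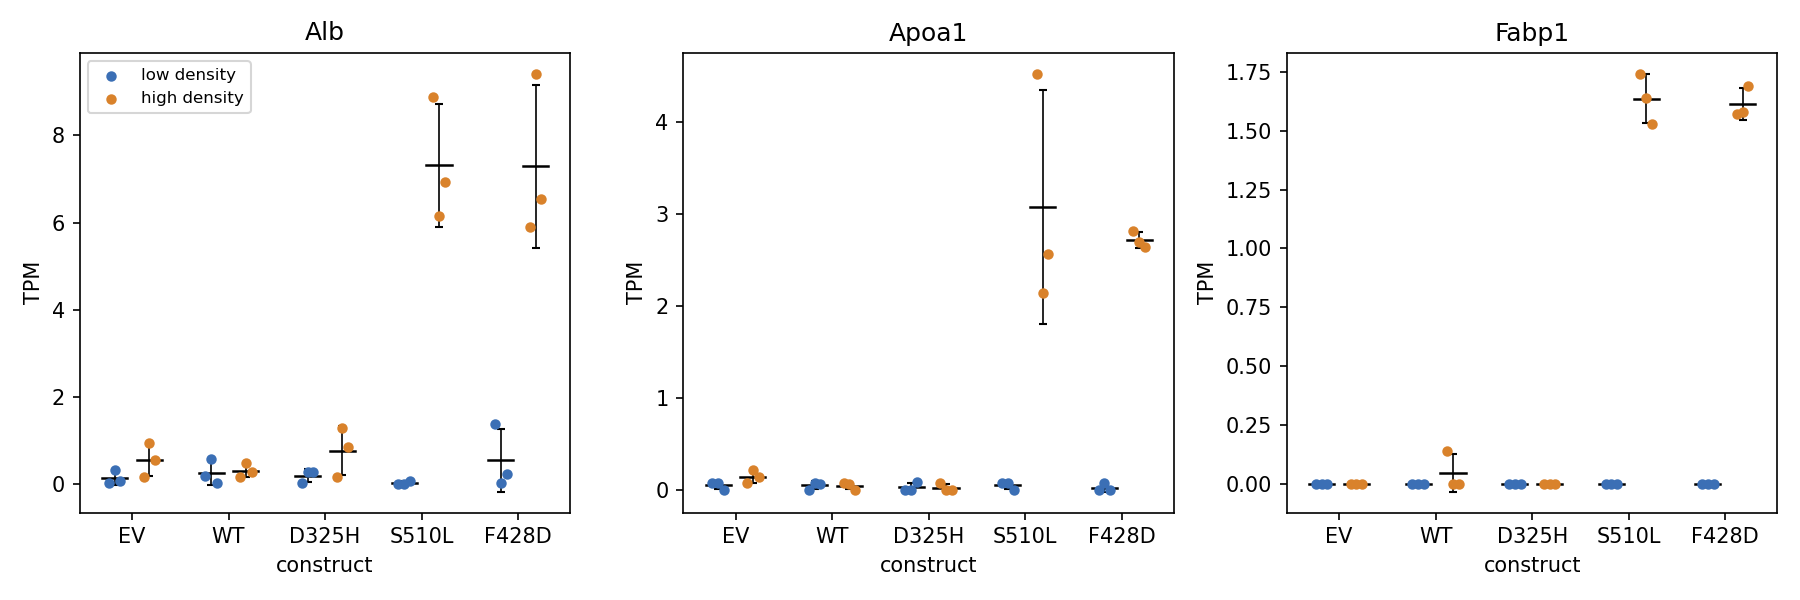
TPM of Alb, Apoa1 and Fabp1 in the 10 groups, points standing for libraries and bars for mean ± SD of 3 libraries. Alb averaged 7.31 TPM in S510L high and 7.29 in F428D high, and 0.774 or less elsewhere.

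Each changed protein was also compared with EV over both densities (n = 6 libraries a side, as between proteins). With D325H, 3568 genes differed, 1641 higher (46.0%) and 1927 lower, with higher shares of 47.6% and 55.4% after quantile and median-ratio scaling. Cry2 was higher by 4.30 ± 0.24 (limma, BH-adjusted p = 5.76e-11), and Trp53 (-2.48 ± 0.37, adjusted p = 0.000134), Cdkn1a (-2.44 ± 0.41, adjusted p = 0.000365), Mdm2 (-1.57 ± 0.22, adjusted p = 7.61e-05) and Btg2 (-1.63 ± 0.16, adjusted p = 2.4e-06) were lower. After Cry2 the highest were Mfap4 4.20, Igf2 3.61, Penk 2.88 and Ccn3 2.87, and the 5 lowest Ass1 -2.73, Ltc4s -2.70, Prl2c3 -2.62, Cd80 -2.58 and Anxa8 -2.49 (limma, adjusted p = 3.59e-06 to 0.00521). Cdkn2a (0.69), Per2 (0.65) and Dbp (0.85) were higher, and Cry1 0.17, Myc -0.10 and Nr1d1 0.20 not called (adjusted p = 0.33 to 0.804). The p53 target genes gave 1 higher and 22 lower of 27 (2 and 23 adjusted over the list alone), Sesn1 being higher (0.35). The median was -1.29 (camera adjusted p = 1.54e-14, adjusted p = 0.215 with an estimated correlation). Contractile genes gave 12 higher and 0 lower of 14 (13 and 0 adjusted over the list alone). The median was 0.98 (camera adjusted p = 1.18e-12, adjusted p = 0.2 with an estimated correlation). MYC target genes gave 0 higher and 21 lower of 23 (0 and 23 adjusted over the list alone). The median was -0.56 (camera adjusted p = 7.02e-11, adjusted p = 0.245 with an estimated correlation). Collagen and matrix genes gave 13 higher and 1 lower of 20 (13 and 1 adjusted over the list alone), Fn1 being lower (-0.45). The median was 0.89 (camera adjusted p = 1.58e-08, adjusted p = 0.245 with an estimated correlation). The count was 2215 without D325H low 1 and 2156 without D325H high 2, which also ended the Cdkn2a call (adjusted p = 0.0521).

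S510L over both densities differed from EV in 2629 genes, 1888 higher (71.8%) and 741 lower, with higher shares of 54.6% and 56.3% after quantile and median-ratio scaling. Matn1 was at 117 ± 88.0 against 6.32 ± 5.81 TPM (4.07 ± 0.47, limma, BH-adjusted p = 3.66e-06), and Col9a3 3.43, Rtl3 3.42 and Hapln1 3.38 were also among the highest. The 5 lowest were Maob, a monoamine oxidase (-2.70 ± 0.41, adjusted p = 6.52e-05), and Mgst1 -2.62, Adam23 -2.24, Sncg -2.18 and Ugt1a7c -2.00 (limma, adjusted p = 0.00014 to 0.00379 for the other genes). Cry2 was higher by 2.13 ± 0.24 (adjusted p = 2.63e-06), and Trp53 (-1.98 ± 0.37, adjusted p = 0.000546), Cdkn1a (-1.70 ± 0.41, adjusted p = 0.00504) and Mdm2 (-0.99 ± 0.22, adjusted p = 0.00239) were lower. Nr1d1 was higher (0.67, adjusted p = 0.048), and Cry1 0.29, Myc -0.18, Cdkn2a 0.31, Per2 -0.10 and Dbp 0.26 were not called (limma, adjusted p = 0.117 to 0.666). The p53 target genes gave 0 higher and 18 lower of 27 (2 and 21 adjusted over the list alone). The median was -0.99 (camera adjusted p = 3.1e-14, adjusted p = 0.347 with an estimated correlation). Adipocyte markers gave 0 higher and 5 lower of 8 (0 and 6 adjusted over the list alone). The median was -0.87 (camera adjusted p = 6.01e-05, adjusted p = 0.347 with an estimated correlation). Skeletal lineage genes gave 7 higher and 1 lower of 10 (7 and 1 adjusted over the list alone), Alpl being lower (-1.23). The median was 1.22 (camera adjusted p = 0.00129, adjusted p = 0.456 with an estimated correlation). The Nr1d1 call ended in 9 of the 12 fits without 1 library, with adjusted p from 0.0519 (EV low 3) to 0.153 (S510L low 1), and after quantile (0.0841) and median-ratio scaling (0.0805).

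F428D over both densities differed from EV in 869 genes, 224 higher (25.8%) and 645 lower, with higher shares of 48.2% and 48.1% after quantile and median-ratio scaling. Cry2 was higher by 3.99 ± 0.24 (limma, BH-adjusted p = 2.92e-10), and Cry1 was lower, at -1.05 ± 0.12 (adjusted p = 4.88e-05). After Cry2 the highest were Slc16a11 1.89, Stmn2 1.72, Serinc2 1.66 and Rcan2 1.49, Stmn2 being a microtubule regulator of neurons (10.1 ± 4.85 against 2.15 ± 0.900 TPM). The 5 lowest were Ecrg4 -2.73, Igf2 -2.34, Apoe -2.15, Grem1 -2.13 and Pdgfra -1.99 (limma, adjusted p = 0.00188 to 0.0445 for these 9). Cdkn2a was lower (-0.71 ± 0.20, adjusted p = 0.0363), and Trp53 0.05, Cdkn1a 0.41, Mdm2 -0.06, Myc -0.31, Per2 -0.31, Nr1d1 0.56 and Dbp -0.48 were not called (adjusted p = 0.122 to 0.951). Of the p53 target genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), the lower one being Sesn1 (-0.40). The median was 0.04 (camera adjusted p = 0.254). Adipocyte markers gave 0 higher and 2 lower of 8 (0 and 5 adjusted over the list alone), with Lpl at -1.69. The median was -0.74 (camera adjusted p = 0.00235, adjusted p = 0.607 with an estimated correlation). The count was 398 without EV low 2, 420 and 462 without EV high 2 and 3, 1380 without F428D low 1, 322 without F428D high 2 and 404 with only the groups compared fitted. The Cdkn2a call ended in 8 fits without 1 library (adjusted p = 0.0588 without EV low 3 to 0.111 without F428D high 2).

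Between the changed proteins, D325H and S510L differed in 3227 genes, 851 higher with D325H (26.4%) and 2376 lower, with higher shares of 46.7% and 54.3% after quantile and median-ratio scaling. Higher with D325H were the matrix gene Dpt (3.04 ± 0.47, limma, BH-adjusted p = 0.000106) and Susd2 2.84, Aoc3 2.81, Gdpd2 2.63 and Mfap4 2.58. Lower were Acan -3.12, Col9a1 -3.12, Hapln1 -3.01, Frzb -2.96 and Matn1 -2.96 (limma, adjusted p = 5.4e-06 to 0.00147 for these 9), Frzb being a Wnt antagonist of cartilage. Cry2 (2.17 ± 0.24, adjusted p = 4.52e-06) and Per2 (0.75 ± 0.12, adjusted p = 0.000176) were higher, and Trp53 -0.50, Cdkn1a -0.74, Mdm2 -0.58, Cdkn2a 0.38, Cry1 -0.11, Myc 0.08, Nr1d1 -0.47 and Dbp 0.59 were not called (adjusted p = 0.0594 to 0.853). ATF4 stress genes gave 0 higher and 12 lower of 17 (0 and 15 adjusted over the list alone), with Trib3 lower, at -1.36 ± 0.15 (limma, adjusted p = 4.52e-06). The median was -0.61 (camera adjusted p = 6.54e-07, adjusted p = 0.279 with an estimated correlation). Skeletal lineage genes gave 0 higher and 6 lower of 10 (0 and 6 adjusted over the list alone). The median was -1.13 (camera adjusted p = 0.000512, adjusted p = 0.279 with an estimated correlation). Of the p53 target genes, 0 were higher and 2 lower (0 and 1 adjusted over the list alone). The median was -0.25 (camera adjusted p = 0.129). The calls of the S phase genes E2f1 and Mcm2 and of Ccna2, Insig1 and Dhcr7 ended after quantile or median-ratio scaling, and the count was 2005 without D325H low 1, 2069 without D325H high 2 and 2147 without S510L high 2.

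D325H and F428D differed in 4702 genes, 2787 higher with D325H (59.3%) and 1915 lower, with higher shares of 50.0% and 56.4% after quantile and median-ratio scaling. Igf2 was higher by 5.95 ± 0.52 (limma, BH-adjusted p = 1.27e-07), followed by Mfap4 5.16, Postn 4.51, Mest 4.35 and Dpt 4.04, and the 5 lowest were Sprr1a -3.25, Prl2c2 -3.20, Prl2c3 -3.11, Anxa8 -2.89 and Perp -2.86 (limma, adjusted p = 8.96e-08 to 0.00133 for these 9). Trp53 (-2.54 ± 0.37, adjusted p = 3.11e-05), Cdkn1a (-2.85 ± 0.41, adjusted p = 2.98e-05) and Mdm2 (-1.51 ± 0.22, adjusted p = 2.97e-05) were lower, and Cry1 1.23, Cdkn2a 1.40, Per2 0.96 and Dbp 1.33 higher (limma, adjusted p = 6.92e-07 to 0.000414). Cry2, Myc and Nr1d1 were not called (adjusted p = 0.246 to 0.539). The p53 target genes gave 1 higher and 21 lower of 27 (2 and 22 adjusted over the list alone), Sesn1 being higher (0.75). The median was -1.23 (camera adjusted p = 4.82e-14, adjusted p = 0.237 with an estimated correlation). Collagen and matrix genes gave 14 higher and 1 lower of 20 (16 and 1 adjusted over the list alone), Fn1 being lower (-0.49). The median was 1.06 (camera adjusted p = 1.33e-07, adjusted p = 0.237 with an estimated correlation). The count was 2616 with only the groups compared fitted.

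S510L and F428D differed in 4721 genes, 3593 higher with S510L (76.1%) and 1128 lower, with higher shares of 52.9% and 55.1% after quantile and median-ratio scaling, which moved the median of all genes by -0.115 and -0.106. Among the highest were Igf2 5.64, Matn1 5.05, Col9a1 4.79 and Snorc 4.69, and the 5 lowest Sprr1b -3.58, Sprr2k -2.82, Cox6b2 -2.57, Irx2 -2.41 and Sprr1a -2.35 (limma, BH-adjusted p = 1.57e-07 to 0.0325 for those named). Trp53 (-2.03 ± 0.37, adjusted p = 0.000213), Cdkn1a (-2.11 ± 0.41, adjusted p = 0.000434), Mdm2 (-0.94, adjusted p = 0.00215) and Cry2 (-1.86, adjusted p = 4.63e-06) were lower, and Cry1 1.34, Cdkn2a 1.02 and Dbp 0.74 higher (limma, adjusted p = 1.57e-07 to 0.0278). Myc, Per2 and Nr1d1 were not called (adjusted p = 0.197 to 0.756). The p53 target genes gave 1 higher and 20 lower of 27 (2 and 20 adjusted over the list alone), Sesn1 being higher (0.62). The median was -1.04 (camera adjusted p = 4.54e-13, adjusted p = 0.568 with an estimated correlation). Skeletal lineage genes gave 7 higher and 1 lower of 10 (7 and 1 adjusted over the list alone). The median was 1.59 (camera adjusted p = 0.00759, adjusted p = 0.578 with an estimated correlation).

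High density, harvested on day 11, was compared with low density, harvested on day 14, over the 5 constructs (n = 15 libraries a side), so density and time in culture change together. Genes numbering 2830 differed, 490 higher (17.3%) and 2340 lower, with higher shares of 48.8% and 41.9% after quantile and median-ratio scaling. Acan was lower at high density, at -2.30 ± 0.32 (limma, BH-adjusted p = 9.42e-05), and so was Col2a1, at -1.57 ± 0.14 (adjusted p = 4.33e-07), the 10 lowest being Cnmd -2.57, Acan -2.30, Hapln1 -2.10, C1qtnf3 -1.93, Col9a3 -1.77, Snorc -1.70, Rtl3 -1.69, Col2a1 -1.57, Igfbp5 -1.57 and Scrg1 -1.57. The 10 highest were Mgst1 1.38, Elobl 1.00, Crocc2 0.99, Il33 0.96, Hp 0.90, Barx2 0.89, Car3 0.86, Prg4 0.70, Igf2bp3 0.69 and Itih2 0.68 (limma, adjusted p = 4.33e-07 to 0.0469 for the 20). Ccn2, a YAP-induced matrix factor, was lower, at -1.03 ± 0.14 (adjusted p = 5.96e-05). Of 13 YAP target genes, 0 were higher and 11 lower (0 and 12 adjusted over the list alone). The median was -0.36 (camera adjusted p = 6.39e-07, adjusted p = 0.372 with an estimated correlation). Skeletal lineage genes gave 0 higher and 6 lower of 10 (0 and 8 adjusted over the list alone). The median was -0.66 (camera adjusted p = 5.05e-05, adjusted p = 0.372 with an estimated correlation). Collagen and matrix genes gave 0 higher and 12 lower of 20 (0 and 16 adjusted over the list alone). The median was -0.46 (camera adjusted p = 5.73e-06, adjusted p = 0.544 with an estimated correlation). The genes Cry2 -0.07, Cry1 -0.20, Myc 0.36, Trp53 0.35, Cdkn1a 0.12, Mdm2 -0.27, Cdkn2a 0.10, Per2 -0.11, Nr1d1 -0.38 and Dbp -0.17 were not called (adjusted p = 0.0679 to 0.773). Of the p53 target genes, 1 was higher and 2 lower (1 and 2 adjusted over the list alone). The median was 0.01 (camera adjusted p = 0.356) and the mean -0.01, Apaf1 (-0.26) and Polk (-0.32) being the lower members.

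**Figure D4:**
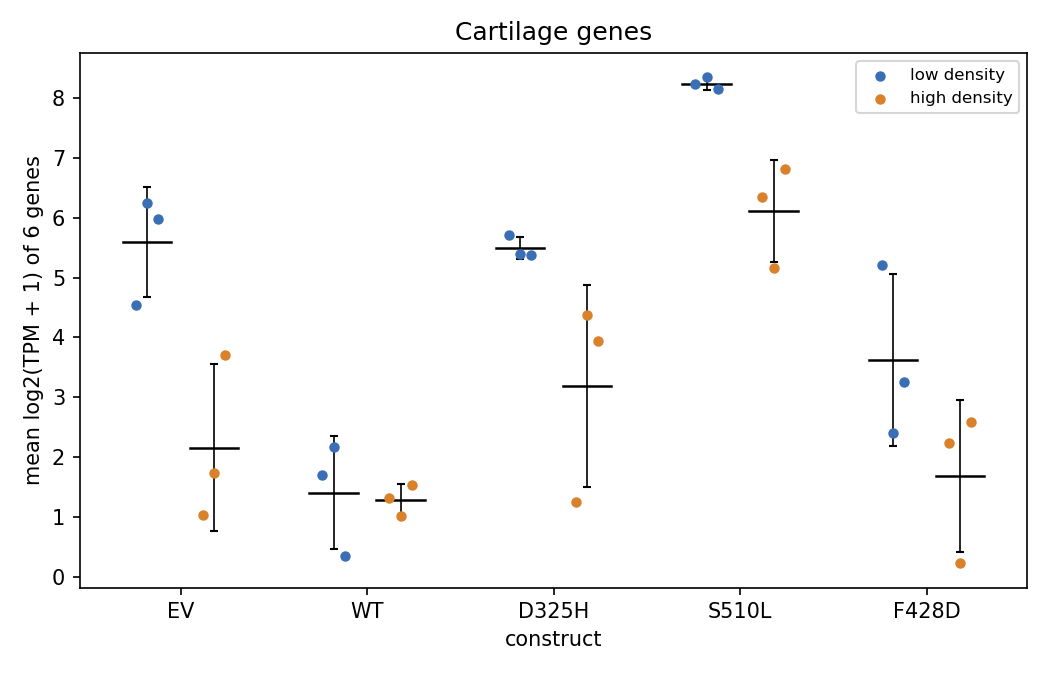
Mean log2(TPM + 1) of 6 cartilage genes in each library (points), with bars for mean ± SD of 3 libraries in the 10 groups. The mean was 8.24 in S510L low and 1.41 in WT low.

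The joint test of whether construct effects differ between densities called 10 genes, with 1082 at unadjusted p under 0.05. They were Apoa1 and Fabp1 (limma, BH-adjusted p = 1.42e-06 each), Alb and Ahsg (0.00022 each), Chrdl2 (0.000595), Serpina1b (0.000788) and, named after their values were seen, Nrk (0.00966), Cyp2e1 (0.0192), Serpina1a (0.0261) and Serpina1c (0.0364). All but Chrdl2 and Nrk, a protein kinase, are in the liver list, and without that list the count was 2. The count was 4 with a pseudocount of 0.1, 45 without the filter on low values and 0 with a filter on mean TPM of at least 5.

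The remaining lists are given for D325H against WT at low density. Clock activators gave 0 higher and 1 lower of 6 (0 and 1 adjusted over the list alone), Arntl being lower with D325H (-1.35), and the mean was -0.05 against a positive median and test. The median was 0.08 (camera adjusted p = 0.948). Inflammatory secretory genes gave 3 higher and 2 lower of 13 (4 and 2 adjusted over the list alone), with Lif at -1.69 and Ptgs2 at -1.61. The median was -0.29 (camera adjusted p = 0.633). Neural markers gave 0 higher and 2 lower of 7 (0 and 2 adjusted over the list alone). The median was -0.28 (camera adjusted p = 0.22). Skeletal muscle markers gave 2 higher and 0 lower of 6 (2 and 0 adjusted over the list alone), Tnnt3, a troponin, standing at 3.51 (6.77e-07). The median was 0.16 (camera adjusted p = 0.148). Epithelial markers gave 0 higher and 1 lower of 5 (0 and 2 adjusted over the list alone). The median was 0.01 (camera adjusted p = 0.355) and the mean -0.91, with Krt19 at -2.58. Adipocyte markers gave 0 higher and 3 lower of 8 (0 and 3 adjusted over the list alone). The median was -0.44 (camera adjusted p = 0.149). Of endothelial and macrophage markers 1 gene each was tested, Egfl7 (0.27) and Cd68 (-0.41), with 0 called in the D325H comparison (limma, adjusted p = 0.421 and 0.359), and no list test.

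The other lists called in limma camera follow with median and adjusted p, and all lost their calls with an estimated correlation (adjusted p = 0.237 to 0.923). WT against EV at low density had cholesterol (-0.13, 0.0219). WT against EV at high density had collagen (-0.14, 0.0466) and ATF4 (0.16, 0.00949). D325H against WT at low density had YAP (0.27, 0.0479). S510L against WT at high density had S phase (0.44, 0.00384) and collagen (0.58, 0.0289). F428D against WT at low density had S phase (-0.27, 7.19e-05), G2 (-0.33, 0.000635), collagen (0.29, 0.00267), contractile (0.22, 0.021), YAP (0.15, 0.0192), interferon (0.16, 0.0217) and hypoxia (0.13, 0.00661). D325H against EV had clock repressors (0.50, 0.000171), S phase (-0.31, 0.00532), G2 (-0.28, 0.0276), YAP (0.23, 0.0221), interferon (0.60, 7.02e-07), cholesterol (0.20, 0.0175), ATF4 (-0.33, 0.000219), NRF2 (-0.54, 0.000538) and adipocyte (-0.49, 0.0415). S510L against EV had cholesterol (0.48, 5.33e-08), G2 (0.32, 0.0372), MYC (-0.17, 0.0141), collagen (0.39, 0.0362), contractile (0.43, 0.00129) and NRF2 (-0.14, 0.0372). F428D against EV had hypoxia (-0.23, 0.0177), G2 (-0.33, 0.0335), interferon (0.19, 0.0291) and inflammatory (0.27, 0.0319). D325H against S510L had clock repressors (0.05, 0.0446), S phase (-0.51, 8.67e-06), G2 (-0.63, 1.52e-05), MYC (-0.47, 1.36e-05), collagen (0.27, 0.000126), contractile (0.55, 1.17e-06), interferon (0.44, 0.000126), cholesterol (-0.31, 0.00129), muscle (0.26, 0.00957) and neural (-0.55, 0.0123). D325H against F428D had clock repressors (0.77, 3.76e-05), MYC (-0.33, 1.85e-06), contractile (1.10, 1.33e-07), interferon (0.60, 0.00842), hypoxia (0.35, 0.00948), cholesterol (0.28, 0.0103), ATF4 (-0.32, 0.000352) and NRF2 (-0.54, 3.76e-05). S510L against F428D had clock repressors (0.73, 0.0195), S phase (0.49, 0.00949), G2 (0.64, 0.00183), collagen (0.67, 0.00949), hypoxia (0.35, 0.0287), cholesterol (0.59, 2.78e-06) and NRF2 (-0.11, 0.00575). Density had S phase (0.17, 1.33e-06), G2 (0.26, 2.27e-07), MYC (0.14, 2.81e-06), contractile (-0.41, 0.000144), cholesterol (-0.16, 0.0465), NRF2 (0.10, 0.0228) and adipocyte (0.20, 0.00414).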

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

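The tests of scaling, of the neighbours of Trp53, of Trp53 with its targets, of liver genes at both densities, of a batch and of founder cells were chosen after their results had been seen, and the liver and cartilage lists after those patterns had been. Results are listed here because the effect of a construct differed between densities in a test of that difference, in which density and harvest day change together.

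The F428D effect against WT was larger at high density for the liver genes Alb (2.42), Apoa1 (1.86), Fabp1 (1.32), Ahsg (1.12) and Serpina1b (0.977), in log2(TPM + 1). The S510L effect differed for 10 genes, the F428D effect for 5, and the joint test over constructs called 10.

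Gene lists differed in 33 of 80 camera tests, and 0 of them held with an estimated correlation (adjusted p = 0.155 to 0.974, limma camera after Benjamini-Hochberg). The median differences, high minus low density, for WT against EV were 0.125 (p53 targets), 0.138 (hypoxia and glycolysis), 0.213 (ATF4 stress) and 0.930 (skeletal lineage). For D325H against WT they were 0.226 (p53 targets), 0.389 (S phase), 0.605 (G2 and mitosis), 0.336 (MYC targets), -0.817 (collagen and matrix), -0.736 (contractile), -0.343 (YAP targets), -0.490 (interferon), -0.253 (hypoxia and glycolysis), 0.322 (cholesterol synthesis), 0.343 (NRF2), 0.485 (adipocyte) and -0.908 (skeletal lineage). For S510L against WT the values were 0.360 (p53 targets), -0.544 (clock repressors and E-box outputs), 0.371 (S phase), 0.364 (MYC targets), -0.469 (collagen and matrix), -0.231 (hypoxia and glycolysis), -0.236 (cholesterol synthesis), 0.445 (NRF2), -0.451 (skeletal muscle) and -0.546 (skeletal lineage). F428D against WT gave 0.239 (S phase), 0.293 (G2 and mitosis), 0.261 (MYC targets), -0.271 (collagen and matrix), -0.204 (YAP targets) and -1.02 (skeletal lineage).

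For the low Trp53 and p53 target values with D325H and S510L, scaling was excluded as the cause: over 4 comparisons and 3 scalings the list median was never above -1.04. Trp53's 19 tested neighbours within 200 kb had medians of -0.097 (D325H, -0.52 to 2.1) and 0.09 (S510L, -0.49 to 2.2) at low density. This argues against losing all 19, but not fewer or part of Trp53. Across the 6 libraries of a construct, Trp53 followed the mean of its targets (D325H r = 0.974, exact permutation p = 0.00139, adjusted 0.00278, rho = 1, p = 0.00278, and r = 0.984 without D325H low 3 and D325H high 3; S510L r = 0.93, p = 0.0153, adjusted 0.0153, rho = 0.943, p = 0.0167, 2 relations tested), but the S510L relation rests on S510L low 2 and S510L high 1, without which r = 0.362. These 6 span both densities, and deviations from density means gave r = 0.999 and 0.918 (exact p = 0.0278 each, the lowest 36 orders allow; with ranks within a density r = 1, p = 0.0556). No other gene set was compared, so this does not single out p53 activity. Nor does it separate a mixture of cells from a graded change, or the protein from a cell line's history.

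Liver transcripts marked all 6 libraries of S510L high and F428D high. Of 5 genes named for high-density calls, 0 were called at low density, which cannot exclude a smaller effect there. Liver RNA would raise most liver genes: 18 of 26 not seen before (69.2%) were highest in both groups, under the 80% set beforehand, so this stays open. Gc, Kng1, Cyp1a2, Serpinc1 and others do not follow, but values elsewhere could mask a rise. The list summed to 40.1 to 57.3 TPM in the 6 libraries and 5.64 to 33.8 in the other 24. A batch cannot be told from the groups, since 0 groups hold libraries both with and without the transcripts.

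Cartilage genes differed between libraries of a group. Over deviations from group means in 30 libraries, 9 check genes followed a score of 6 others (r = 0.938, permutation p = 2e-05, rho = 0.908, p = 7e-05, r = 0.917 without the 2 farthest libraries), so these genes moved together, which does not separate a share of cartilage-like cells from a graded change. Few founder cells per well at low density stays open: the SD of the score was larger there in 2 of 5 constructs, from 3 libraries each, but the median SD of all genes in 5 of 5, a bound added after both were known. The score was 5.59 (SD 0.916) in EV low and 1.41 (SD 0.946) in WT low, and no biological explanation was tested.

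Regrouping the libraries gives the number of splits that call at least as many genes, the real one included. With 10 splits there are too few for a share under 0.05, and a split calling many more genes than the real one points to structure among the samples. For WT against EV at low density 2 of 10 did (highest other 122, real 43), at high density 1 (0, real 4). For D325H against WT 1 at low (highest other 1782, real 4081) and 1 at high (0, real 1436). For S510L against WT 1 at low (7, real 3277) and 1 at high (1, real 1293). For F428D against WT 4 at low (3017, real 2), where the split with most calls set WT low 1, WT low 3 and F428D low 3 against the rest, and 1 at high (0, real 9). Of 100 drawn splits, 1 did for D325H against EV (2365, real 3568), S510L against EV (664, real 2629), F428D against EV (155, real 869), D325H against S510L (1661, real 3227), D325H against F428D (2588, real 4702), S510L against F428D (3193, real 4721) and density (2, real 2830), and 5 for the joint test (489, real 10), where chance is not excluded.

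The p53 list median was regrouped likewise. Of 10 splits, WT against EV had 2 at low (highest other 0.179, real 0.153) and 1 at high (0.209, real 0.249), D325H against WT 1 (1.05, real 1.42) and 1 (0.771, real 1.23), S510L against WT 1 (0.633, real 1.41) and 1 (0.477, real 1.02), and F428D against WT 2 (0.22, real 0.169) and 2 (0.131, real 0.11). Of 100, there were 1 for D325H against EV (1.15, real 1.29), S510L against EV (0.776, real 0.992), D325H against F428D (1.02, real 1.23) and S510L against F428D (0.808, real 1.04), 56 for F428D against EV (0.183, real 0.0417), 36 for D325H against S510L (0.657, real 0.252) and 86 for density (0.285, real 0.0148).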

How the results depend on the processing

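Gene-by-gene array weights, leaving out the 2 libraries with the fewest genes and leaving out liver genes were chosen after seeing the data. Values are numbers of genes called, or the median log2 difference of the p53 targets. Where a value moved, the cause was not tested unless called genes had left the fit.

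With a pseudocount of 0.1 the counts were 2 (WT against EV, high), 1 (F428D against WT, low) and 4 (joint test), and with 5, 12 (WT against EV, low). Without the filter they were 5 and 7 (WT against EV, low and high), 4 and 37 (F428D against WT, low and high) and 45 (joint test), and the p53 median of D325H against S510L, -0.252, passed (limma camera, adjusted p = 0.0235). With mean TPM of at least 5 they were 2 (WT against EV, high), 0 (F428D against WT, high) and 0 (joint test), the liver genes no longer being tested. Quantile normalization gave 27 and no variance trend 19 for WT against EV at low density. With only the groups compared fitted the counts were 2 and 22 (WT against EV, low and high), 247 (D325H against WT, low), 1182 and 2852 (S510L against WT, low and high), 0 and 3 (F428D against WT, low and high), 404 (F428D against EV) and 2616 (D325H against F428D), with fewer libraries behind the spread. Without the 2 libraries F428D against EV gave 278, and the p53 median of D325H against S510L passed at -0.323 (adjusted p = 0.0198). Without liver genes F428D against WT at high density gave 0 and the joint test 2.

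Array weights did not converge (weights from 1.27e-07 for F428D low 2 to 17.5 for WT low 1), and their counts are not a measure of the data: 2819 and 1709 (WT against EV, low and high), 10529 and 3961 (D325H against WT), 9765 and 5811 (S510L against WT), 1 and 124 (F428D against WT), 6710, 6749 and 241 (D325H, S510L and F428D against EV), 7732 (D325H against S510L), 4705 (density) and 8490 (joint test), with p53 medians of -0.317 (D325H against S510L, adjusted p = 0.0225) and 0.227 (density, 0.00585, limma camera). Gene-by-gene weights, from 0.2 (F428D low 1) to 3.45 (F428D low 2), ranked F428D low 2 the other way and gave 452 and 1446, 7511 and 3387, 6402 and 4793, 69 and 50 in the same order, then 5822, 5618 and 3586, 5854, 7207 (D325H against F428D), 7314 (S510L against F428D), 6097 and 4602, with p53 medians of -0.324 (adjusted p = 0.0204) and 0.103 (0.0383).

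With an estimated correlation the called p53 medians lost their calls at 0.249 (WT against EV, high), -1.42 and -1.23 (D325H against WT), -1.41 and -1.02 (S510L against WT), -1.29 and -0.992 (D325H and S510L against EV), -1.23 and -1.04 (D325H and S510L against F428D), and 1 list test of 300 stayed called, against 124.

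The replicate number as a block gave 23 (WT against EV, low) and 1 (F428D against WT, low), and 125 list tests. Numbers were checked as a pairing: over 135 pairs of libraries with the same number the deviations from group means correlated at r = 0.0125 on average (-0.39 to 0.555), 40 pairs were over 0.1, and 11 of 30 libraries were closest to 1 of their own number, so libraries share only a number.

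Leaving out each library in turn gave counts of 2 to 85 and 1 to 5 (WT against EV, low and high), 2184 to 4964 and 253 to 1416 (D325H against WT), 2054 to 3394 and 572 to 1030 (S510L against WT), 0 to 6 and 8 to 11 (F428D against WT), 2156 to 4469, 1996 to 2785 and 322 to 1380 (D325H, S510L and F428D against EV), 2005 to 4307 (D325H against S510L), 3566 to 5760 and 3938 to 5125 (D325H and S510L against F428D), 2127 to 4095 (density) and 6 to 17 (joint test). The p53 medians in the same order ran from 0.0904 to 0.216, 0.245 to 0.305, -1.71 to -1.22, -1.48 to -0.976, -1.48 to -1.18, -1.16 to -0.745, -0.264 to -0.101, -0.135 to -0.0743, -1.49 to -1.15, -1.05 to -0.836, -0.0158 to 0.072, -0.474 to -0.155, -1.41 to -1.10, -1.11 to -0.956 and -0.0436 to 0.105. That of D325H against S510L passed without D325H low 3 (-0.474, limma camera, adjusted p = 0.000212), S510L low 2 (-0.311, 0.019) or D325H high 3 (-0.323, 0.0166), and that of density without D325H low 3 (0.105, 0.0174).

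For the named genes, other settings left 9706 values with the same call, 303 weaker, 310 stronger and 0 reversed, and leaving out a library 7865 the same, 532 weaker, 105 stronger and 0 reversed. Depth is not known from TPM and limits genes of low TPM most.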

Other observations

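The correlation across genes between constructs was chosen after the results had been seen.

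The cartilage score, mean log2(TPM + 1) of 6 genes, was 8.24 (SD 0.0994) in S510L low and 6.11 (0.853) in S510L high, 5.50 (0.187) and 3.19 (1.69) with D325H, 3.63 (1.44) and 1.68 (1.27) with F428D, and 2.16 (1.39) in EV high and 1.29 (0.265) in WT high, n = 3 each.

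One hypothesis was that D325H and S510L share changes. D325H and S510L compared with the same WT libraries would share the error of that control, so D325H minus WT was set against S510L minus EV. Across 14093 genes r was 0.467 (covariance 0.0995), and D325H minus WT with F428D minus EV gave r = -0.33 (covariance -0.0546). Genes are not independent replicates, and cell lines with low Trp53 by chance could give the same value, so 0.467 suggests shared changes without saying that the proteins cause them.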
